A study of Homo sapiens with 3 samples.

How the data were processed

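CRISPR-Cap and STAP-seq measurements were made in HEK293T, a human embryonic kidney cell line. In CRISPR-Cap, Cas9 ribonucleoprotein with 1 guide RNA per target was transfected in 2 rounds, which leaves small deletions at an endogenous promoter. In every target the most deleted base lay downstream of the most used unedited start. Capped RNA 5′ ends were then read by gene-specific reverse transcription, per the labels' protocols. The cap was removed and an RNA oligonucleotide ending in 8 random bases was ligated to the freed 5′ end. Because the RNA is read from its 5′ end through the edited sequence, a read gives both the start position and the allele. STAP-seq reads the start positions of RNA made from reporter plasmids. The labels list 2 CRISPR-Cap libraries and 1 STAP-seq library. The protocol given for STAP-seq repeats the CRISPR-Cap text, so the plasmid, the transfection and the input amounts are not given in the sources used here.

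The authors deposited the CRISPR-Cap data as a list with 1 line per 5′ end, holding its class (with or without a deletion), its position, the edges and length of the deletion and the target name. Whether a line is a read or a molecule collapsed by its random bases is not given in the sources used here. The STAP-seq data were deposited as raw counts of 5′ ends per base for 6 constructs, per the file headers. Per the submitters' processing notes, STAR and the hg38 genome build were used; versions and settings are not given in the sources used here. Insertions and genomic DNA counts were not analysed here.

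The deposited list pools the 2 CRISPR-Cap libraries and has no column that separates them. The count model with replicate blocks that had been planned before the data were examined therefore could not be fitted, the agreement of the replicates could not be computed, and no error below comes from separate cultures. In its place, each share carries a Wilson 95% interval, and each difference between edited and unedited ends carries a 95% interval from 1000 bootstrap draws of the deletions of a target and of its unedited ends. These intervals cover counting and the spread between deletions only. If lines are PCR reads, they are not independent molecules and the intervals are too narrow. A target was called lower or higher when its interval excluded 0. Targets were the units of an exact two-sided sign-flip permutation test of the mean over targets. All of these choices were made after the structure of the list was seen, as were the settings described next.

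Positions were treated as counted from 0: adding 1 put 74.3% of the unedited ends on a purine that follows a pyrimidine, the usual initiation dinucleotide, against 1.16% without it. Every coordinate printed is counted from 1 on hg38. Strand, gene and sequence came from GENCODE release 29. Deletions were taken at the edges given. They appeared to be placed at the lowest possible coordinate, since 44.8% of the distinct deletions could be moved to a higher coordinate without changing the allele and 4.83% to a lower one. For a deletion that can be moved, this gives the fewest bases between 5′ end and deletion on the plus strand and the most on the minus strand. Cuts on this distance are therefore not fully alike between strands.

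Edited ends close to their deletion were rare: 83 of 82114 edited ends had fewer than 6 bases between the 5′ end and the deletion, and 375 had fewer than 8. A start that close to a deletion is therefore almost never seen on that allele. Whether its reads are lost, are listed as unedited, or the start is used less was not separated. The class of each line was taken as given. The main comparison was matched for this rarity. For each deletion, edited ends with at least 8 retained bases were compared with unedited ends at the positions that are at least 8 bases upstream of the same deletion, and the expected shares were averaged over deletions by their edited ends. Positions with fewer than 10 ends were left out. The comparison of all ends as tallied is given beside it. The main start of a target is the position with the most unedited ends. It was chosen on the same ends that are compared, which matters where these are few, as in SOCS1 with 4 unedited ends. The upstream shift is the mean position of the matched unedited ends minus that of the edited ends, in bases. A ratio of near to far starts was computed as a Mantel-Haenszel odds ratio over deletions, for starts 8 to 19 bases upstream of the deletion against starts 20 or more bases upstream.

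The matched comparison was tested on simulated data made from the real unedited profiles of 9 targets and their real deletions. In 45 runs without any change the median absolute error was 0.666 percentage points and 95.6% of the intervals held the true value, while the tallied comparison was off by up to −12.7 points. In 45 runs with 30% of the main start moved upstream, the median absolute error was 0.497 points and 93.3% of the intervals held the true value. In all of these runs ends were dropped below 8 retained bases, the same cut that the comparison uses. The runs set no filter on positions, kept the main start fixed and listed no edited end as unedited. They drew all deletions of a target from a common profile. In the real data deletions differ: at C19orf43 the main start held 2.70% to 83.0% among deletions with at least 20 ends. The share of intervals that held the true value may therefore differ in the real data. A partial loss of ends 8 to 19 bases from the deletion was not simulated for the main-start share. The runs therefore do not show that the share is free of such a loss. For the ratio of near to far starts in 8 targets, 24 runs without change gave a median of 0.959, and 24 runs that kept 40% of the near ends gave a median of 0.397.

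Every target is named because there are 13, below the limit of 20 set before the data were examined. The rule also named the most used unedited position of each target and up to 3 positions with the smallest adjusted p. With no p per position, the positions with the largest matched difference were taken instead. Guides and motif classes are not named in the list, so the planned comparison by motif class was not made. The pseudocount planned for classes without ends was not needed. STAP-seq constructs were placed in pairs by their own sequence and matched to GENCODE transcripts over identical stretches. Alternatives covered the filter on positions, the deletion length, the number of retained bases, the weighting of deletions and each target left out in turn. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.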

Results

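The series asks which promoter sequences set where human transcription starts, by editing such sequences in place and reading capped RNA 5′ ends. The CRISPR-Cap list held 131949 capped 5′ ends from 13 targeted promoters in HEK293T cells, pooled from 2 libraries. Of these, 82114 (62.2%) carried a deletion and 49835 did not. Both kinds came from the same transfected cells. Depth differed widely between targets, from 49224 ends at C19orf43 to 70 at SOCS1. In 9 targets there were at least 100 ends of each kind, while IRF1, TXNRD2, EDEM2 and SOCS1 had 31, 35, 53 and 4 unedited ends.

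Deletions were abundant in the RNA of most targets. The edited share of ends exceeded 50% in 10 of 13 targets. It was highest at IRF1, which encodes an interferon-regulated transcription factor (96.6%, Wilson 95% interval 95.2 to 97.6%), and lowest at HIST1H1D, a linker histone gene (20.7%, 19.7 to 21.6%). SOCS1, a cytokine signalling inhibitor, reached 94.3% (86.2 to 97.8%) on few ends. TMED9, a cargo receptor of the early secretory pathway, reached 88.6%, LETMD1 88.3%, NDUFV3, a complex I subunit, 85.3%, and EDEM2 80.7%. TXNRD2, a mitochondrial thioredoxin reductase, had 79.7% (32.7% when only deletions with at least 10 ends were counted), C1orf63 78.7%, RBM4 78.01% and ECI1, an enzyme of mitochondrial fatty acid oxidation, 68.5%. HSF1, the heat shock transcription factor, and C19orf43 were below that level, at 41.5% and 39.6%. On the log2 scale the edited to unedited ratio of ends had a median of 1.97 over the targets, from −1.94 at HIST1H1D to 4.82 at IRF1. Without genomic DNA counts this ratio joins the efficiency of editing with the RNA output of the edited alleles, and these were not separated here. It also depends on where the starts lie, since edited ends close to a deletion were rare and RNA that starts downstream of a deletion cannot show it. At HSF1 the positions 3 and 5 bases downstream of the most used unedited start held 12.4% and 10.9% of the unedited ends. They held 0.305% and 0% of the edited ends.

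The deletion spectrum was particular to each target. There were 2286 distinct deletions. At ECI1 a single 5-base deletion at chromosome 16, 2251573 to 2251577, made up 49.1% of the edited ends (46.8 to 51.3%). At LETMD1 a 9-base deletion (chromosome 12, 51048338 to 51048346) made up 40.1%, at HIST1H1D a 6-base deletion (chromosome 6, 26234889 to 26234894) 38.9%, and at TMED9 the loss of 1 base (chromosome 5, 177592217) 37.8%. C19orf43 had a flat spectrum, in which the most frequent deletion made up 9.49%, and at HSF1 it made up less. Median deletion lengths ran from 2 bases at TMED9 to 23 bases at SOCS1. Deletions of 10 or more bases made up 75.5% of the edited ends at C19orf43 and 7.12% at ECI1.

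All targeted sites lay downstream of the main start, with the most deleted base 9 bases away at HSF1, 94 at HIST1H1D and farther still at C19orf43. On hg38 the main starts of the minus-strand targets were at chromosome 19, 12734742 (C19orf43, now named TRIR), chromosome 1, 25247454 (C1orf63, now RSRP1), chromosome 6, 26234987 (HIST1H1D), chromosome 16, 2251593 (ECI1), chromosome 5, 132490773 (IRF1), chromosome 20, 35278122 (EDEM2), chromosome 22, 19941818 (TXNRD2) and chromosome 16, 11256200 (SOCS1). The plus-strand targets had theirs at chromosome 11, 66616630 (RBM4), chromosome 5, 177592203 (TMED9), chromosome 12, 51048327 (LETMD1), chromosome 21, 42893311 (NDUFV3) and chromosome 8, 144291605 (HSF1). In GENCODE the start labelled RBM4 is that of RBM14 and the RBM14-RBM4 readthrough, and the start labelled EDEM2 is that of MMP24OS. The middle of the deletions lay in annotated untranslated sequence at C1orf63, ECI1, EDEM2, HSF1, IRF1, LETMD1, RBM4 and SOCS1. It lay in sequence annotated as coding in at least 1 transcript at C19orf43, HIST1H1D, NDUFV3, TMED9 and TXNRD2.

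On edited alleles the main start took a smaller part of the 5′ ends in most promoters, and starts farther upstream took a larger part. After matching on at least 8 retained bases, the main-start share was lower in 7 targets, higher in C19orf43, and had an interval that spanned 0 in 5. This cut does not remove the lower relative use of starts 8 to 19 bases from the deletion, which is given below and enters these differences. At RBM4 it fell from 75.6% to 63.02%, a difference of −12.6 percentage points (95% interval −16.4 to −9.13, 26561 edited ends over 221 deletions). At TMED9 it fell from 75.9% to 54.6% (−21.3 points, −33.0 to −13.6), and at C1orf63 from 52.02% to 28.3% (−23.7 points, −30.6 to −15.7). NDUFV3 went from 24.2% to 8.75% (−15.5 points, −18.8 to −12.2) and HSF1 from 14.7% to 10.9% (−3.84 points, −7.55 to −0.372). The differences at IRF1 (27.1% to 3.72%) and EDEM2 (63.3% to 23.3%) were large but rested on 31 and 53 unedited ends. At C19orf43 the share rose from 29.04% to 36.4% (7.32 points, 3.13 to 11.2). A further cluster of starts lies 79 to 82 bases downstream of its main start, and some of its longer deletions run into that cluster, such as 12734616 to 12734665 (542 ends).

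At the other targets the interval spanned 0. LETMD1 had −15.8 points with an interval of −31.6 to 1.07, ECI1 had −5.75 (−11.6 to 2.07) and HIST1H1D had −2.09 (−5.12 to 0.169). With deletions of at least 3 bases only, LETMD1 (−20.3 points) and HIST1H1D (−2.24 points) had intervals below 0 as well, which made 9 targets lower. TXNRD2 had −1.83 points (−14.3 to 11.3) and SOCS1, with 4 unedited ends, −33.5 (−71.5 to 19.1). Over the 13 targets the main-start share was lower in 12, with a median difference of −15.5 points (exact sign-flip test of the mean, two-sided, p = 0.0022, adjusted over 2 tests 0.0034). Every target called lower in the main setting had its most deleted base 9 to 24 bases downstream of the main start, as did LETMD1 and ECI1. At SOCS1, TXNRD2, HIST1H1D and C19orf43 it lay 47 or more bases away, and none of these was called lower. How the fall depends on this distance between targets was not tested. The ends moved upstream with an interval above 0 in 8 targets and downstream in none; at IRF1, 1 of the 8, the shift fell from 7.73 to 4.09 bases with an interval that spanned 0 when no filter was set on positions. The mean shift was 3.53 bases (exact p = 0.0034, adjusted 0.0034), from 1.73 bases at TMED9 to 8.35 at NDUFV3 among the 8. With all ends as tallied the median difference was −23.1 points, LETMD1 also had a lower share, the mean shift was 7.77 bases, and 11 targets had ends moved upstream.

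**Figure D1:**
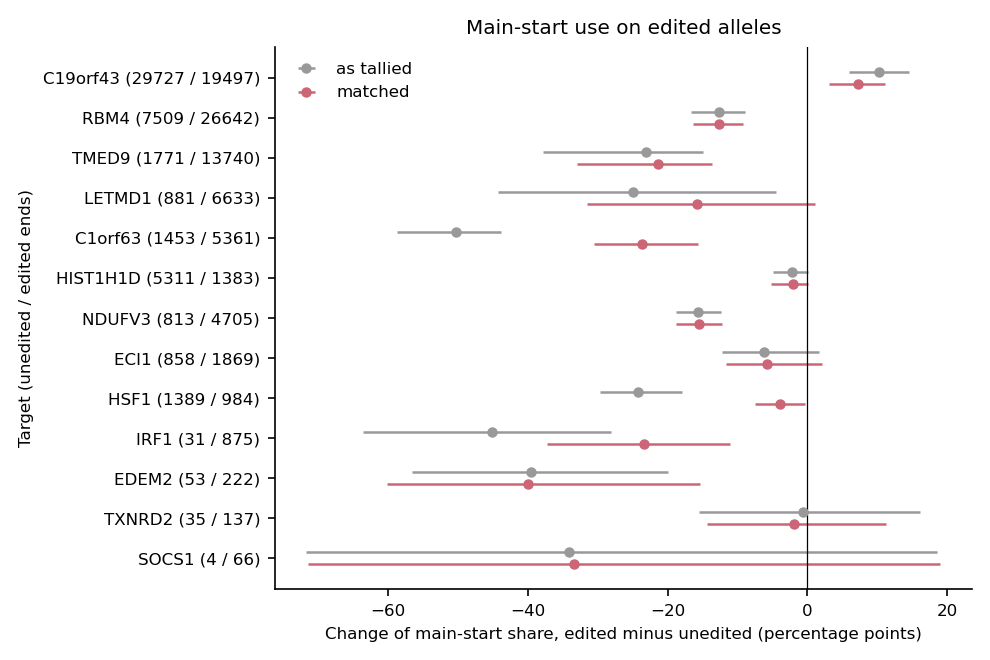
Change of the main-start share (edited minus unedited, percentage points) per target. Points are estimates and bars 95% bootstrap intervals. Grey shows all ends as tallied and red those matched on at least 8 retained bases. Matched intervals lie below 0 in 7 targets and above 0 in C19orf43 alone.

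Over all targets, these 2 results did not pass the test farther from the deletion. When only ends with at least 20 retained bases were compared, the median difference over the 10 targets that could still be measured was −1.09 points (exact p = 0.0879). The mean shift over 13 targets was 0.0370 bases (exact p = 0.967). In that setting the main start held over 5% of the expected ends in only 6 targets. RBM4 (−9.08 points) and NDUFV3 (−10.1 points) were lower among these, and the rise at C19orf43 no longer had an interval above 0. Targets went both ways there: the shift was 4.41 bases at EDEM2, 4.35 at NDUFV3 and 1.79 at RBM4, and −5.66 at LETMD1 and −4.76 at TMED9, each with an interval that excluded 0.

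Apart from C19orf43, the position with the largest matched gain is given for each target. Smaller gains at other positions are mostly left out, and no test was made per position. At C1orf63, position 25247485, 31 bases upstream of the main start, rose from 4.68% (3.71 to 5.89%) of all unedited ends to 34.1% (32.9 to 35.4%) of all edited ends; matched, the rise was from 17.5% to 35.4%. At LETMD1, position 51048318, 9 bases upstream, rose from 2.95% (2.02 to 4.29%) to 29.2% (28.1 to 30.3%), or from 8.11% to 29.9% when matched. RBM4 gained at 66616616, 14 bases upstream, from 2.41% to 9.89% when matched. TMED9 gained at 177592199, 4 bases upstream, from 8.18% to 14.1% when matched, with smaller gains 1 and 6 bases upstream. NDUFV3 gained at 42893272, 39 bases upstream, from 25.5% to 33.5% when matched. HSF1 gained at 144291563, 42 bases upstream, from 2.46% to 6.12% when matched, on 6 unedited and 51 edited ends.

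At EDEM2, position 35278139 held 24.8% (19.6 to 30.9%) of the edited ends and none of the 53 unedited ends, which allows up to 6.76%. At IRF1, position 132490800 held 10.1% (8.24 to 12.2%) of the edited ends and none of the 31 unedited ends, which allows up to 11.03%. At SOCS1, position 11256204 held 57.6% of 66 edited ends and 1 of 4 unedited ends. C19orf43 had lower matched shares at 12734660, 5.60% to 1.17%, and at 12734663, 23.2% to 19.3%; both lie downstream of its main start and near to or within its deletions. At ECI1 and HIST1H1D, whose main-start intervals spanned 0, the largest matched gains were 3.66 points at 2251591 and 2.31 points at 26234989. TXNRD2 had a matched gain of 1.83 points at 19941809.

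**Figure D2:**
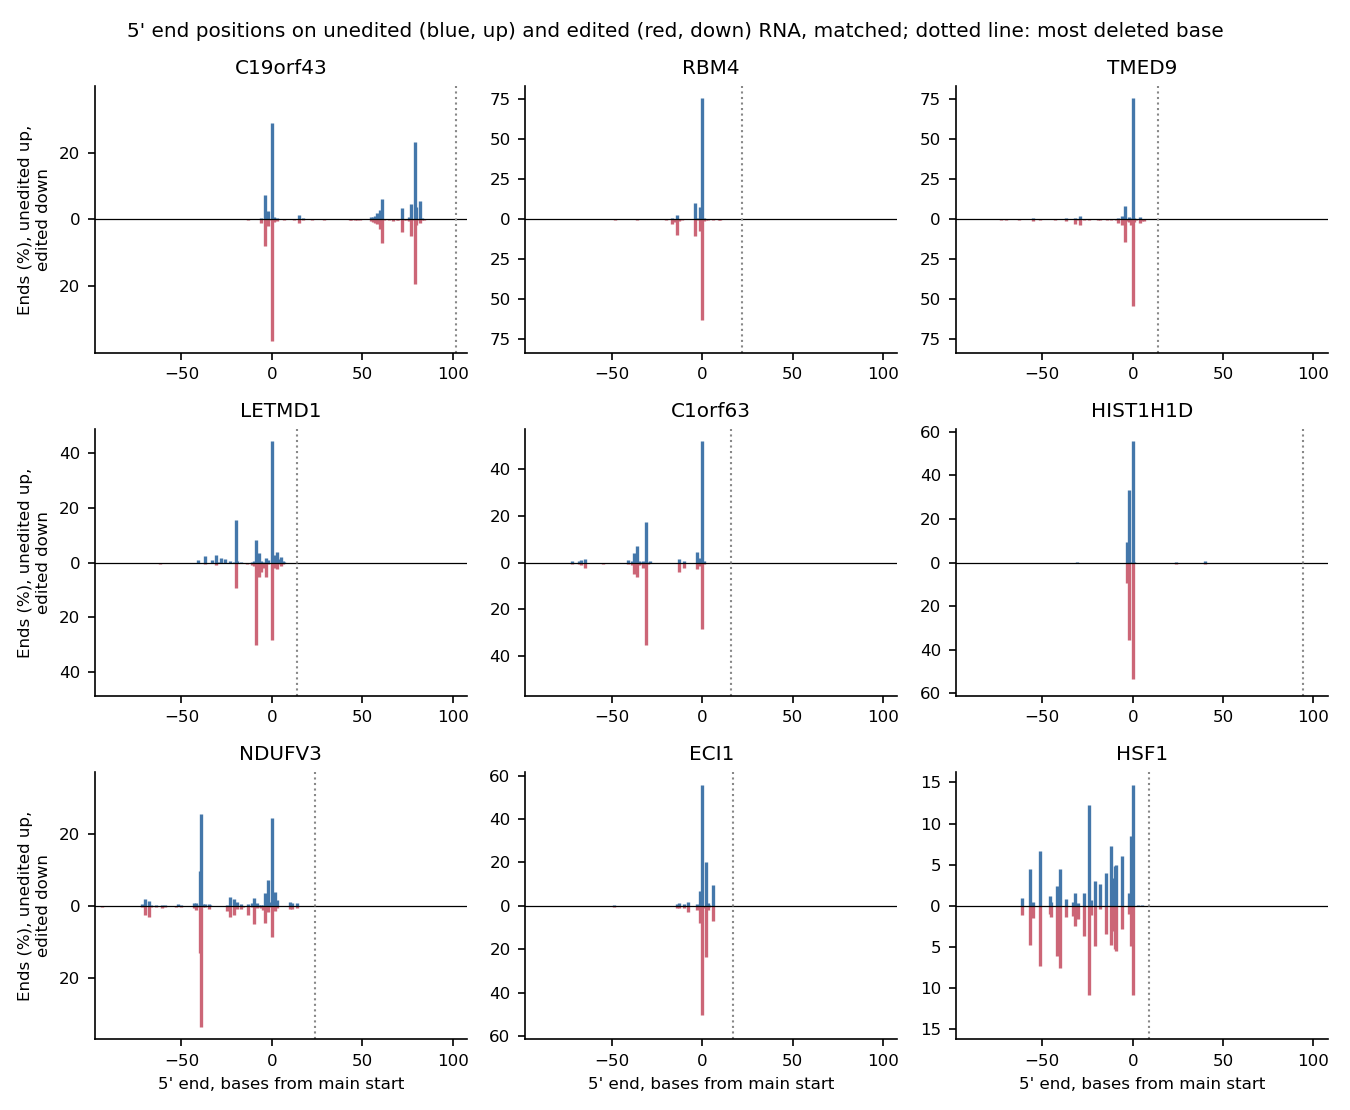
Share of 5′ ends (%) by position relative to the main start (bases) in the 9 targets with at least 100 ends of each kind. Unedited ends point up in blue and edited ends down in red, matched on at least 8 retained bases. The dotted line marks the most deleted base. C1orf63 and LETMD1 show the gains 31 and 9 bases upstream, and HIST1H1D shows nearly the same profile on both alleles.

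Starts near the deletion, summed over 8 to 19 bases, had a lower relative use on edited alleles. For starts 8 to 19 bases upstream of the deletion, relative to starts 20 or more bases upstream, the edited to unedited odds ratio was below 1 in 8 of 8 targets, with a median of 0.416. The exact sign-flip test of the log2 ratios gave p = 0.0078, the smallest p that 8 targets allow. The ratio was lowest at C1orf63 (0.193, 95% interval 0.147 to 0.265) and highest at ECI1 (0.701, 0.477 to 0.992), and these intervals did not overlap. The interval at LETMD1 (0.679, 0.371 to 1.34) included 1. NDUFV3 had 0.346, RBM4 0.352, TMED9 0.404, C19orf43 0.429 and HSF1 0.432, each with an interval below 1. Finer windows were not uniform: for starts 16 to 19 bases upstream the ratio was 2.32 (1.11 to 4.10) at LETMD1 with deletions of 3 to 9 bases, and 2.45 (1.75 to 6.72, on 21 near edited ends) at C19orf43 with deletions of 1 or 2 bases. The other 5 targets had no or too few ends in this range or farther upstream to be measured.

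**Figure D3:**
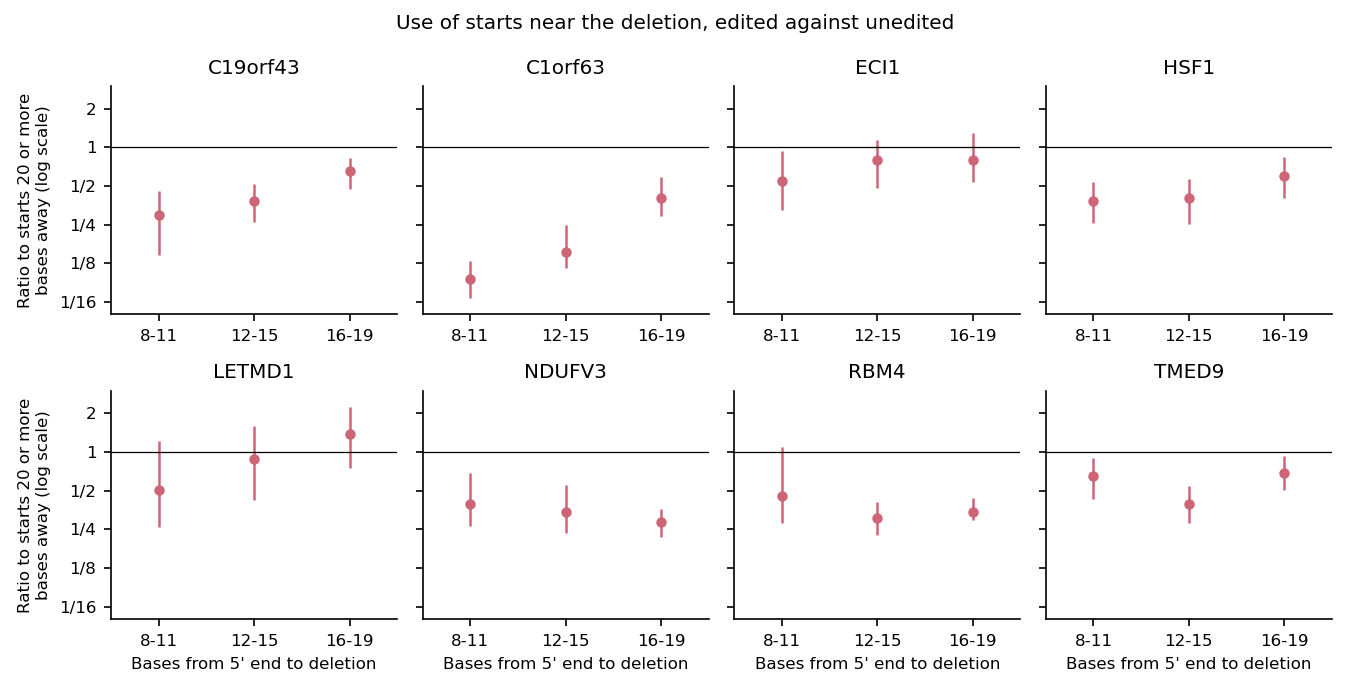
Odds ratio of edited to unedited ends (log scale) for starts 8 to 11, 12 to 15 and 16 to 19 bases upstream of the deletion, each against starts 20 or more bases upstream, in 8 targets; bars are 95% bootstrap intervals. C1orf63 rises from 0.0940 to 0.399 with distance, while NDUFV3 stays between 0.288 and 0.395.

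Longer deletions were compared with shorter ones within a target. Relative to its matched unedited share, the main start kept a median of 0.585 of its use with deletions of 10 or more bases and 0.815 with deletions of 1 or 2 bases, over 7 targets with 100 ends of each. The long deletions gave the lower value in 6 of 7, with a median log2 ratio of −0.55, but the exact sign-flip test gave p = 0.25 (the smallest possible is 0.0156). IRF1 had the largest relative gap, 0.0107 against 0.392, and C19orf43 went the other way, 1.37 against 0.471. The long value at IRF1 rests on a main-start share of 0.185% among 540 edited ends, set against 31 unedited ends.

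The STAP-seq sample held 6 reporter constructs, which by sequence form 3 pairs, each pair identical outside a short block. The pairs match the promoters of FEZ2 (chromosome 2, 36598119 to 36598191, minus strand), HIF1AN (chromosome 10, 100535859 to 100535974, plus strand) and KIF5B (chromosome 10, 32056394 to 32056431, minus strand), where these ranges are the parts found in GENCODE transcripts. FEZ2 encodes a kinesin adaptor, HIF1AN an oxygen-dependent inhibitor of hypoxia-inducible factor, and KIF5B a kinesin heavy chain. Construct coordinates run from 94 to 213. There was 1 library and no plasmid input count, so totals join promoter output with the amount of plasmid, and all intervals cover counting only.

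In the FEZ2 pair the block GGGGGCGG, a GC box, was changed by G106C, G108T, G110C and G113A (first base from the construct with more counts, numbered by construct coordinate). The altered construct gave 38477 counts against 108890, 2.83-fold fewer (2.80 to 2.86). Start positions changed little: 8.51% of the starts were placed differently, the main start stayed at 177 with 18.6% (18.4 to 18.8%) and 17.6%, and the mean position moved upstream by 0.638 bases (0.519 to 0.748).

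In the HIF1AN pair the block AGCTTCCGGT at 159 to 168, which contains an ETS-type core and is the genomic sequence, was replaced by CCACCGTTCG. Counts were 1619777 with the genomic block and 530729 without, a 3.05-fold difference (3.04 to 3.06). Starts downstream of the block fell from 88.8% to 36.2%, and starts upstream of it rose from 5.24% to 48.01%. The rise upstream was also one of counts, from 84911 to 254789, while downstream counts were 7.48-fold lower. Starts within the block rose in share from 5.94% to 15.8%, although their summed counts fell from 96220 to 83659. Counts rose at 161 (264 to 24506) and 168 (92 to 15308), where the replacement put a purine for a pyrimidine (C161A and T168G). Other positions within the block fell, such as 165 (19148 to 63). The main start moved from 188 (16.1% to 7.51%) to 151 (2.18% to 14.8%, 14.7 to 14.9%), position 100535912 on chromosome 10, and the mean position moved upstream by 19.3 bases.

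In the KIF5B pair the block CGCCTGCGC at 151 to 159, which resembles an NRF1 site, was replaced by ATGCATAGT. Counts fell from 598512 to 12867, 46.5-fold (45.7 to 47.3). The main start moved from 201 (22.7% to 11.95%, 11.4 to 12.5%) to 189 (13.6% to 31.97%, 31.2 to 32.8%), and the mean position moved upstream by 9.27 bases (8.96 to 9.56). Starts upstream of the block and within it rose in share, from 0.221% to 2.32% and from 1.09% to 9.50%, but their summed counts were lower, 299 against 1322 upstream and 1222 against 6501 within. Single positions within the block had higher counts: 297 against 3 at 153, and likewise at 151, at 157 (68 against 4) and at 155. Position 155 held 700 counts and went from 0.0197% to 5.44% of the starts. At each of these places the replacement put a purine for a pyrimidine (C151A, C153G, T155A and C157A). New start bases and the loss of the block were therefore not separated. Which member of the FEZ2 and KIF5B pairs is the genomic sequence was not checked, since the transcripts used do not reach these blocks.

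**Figure D4:**
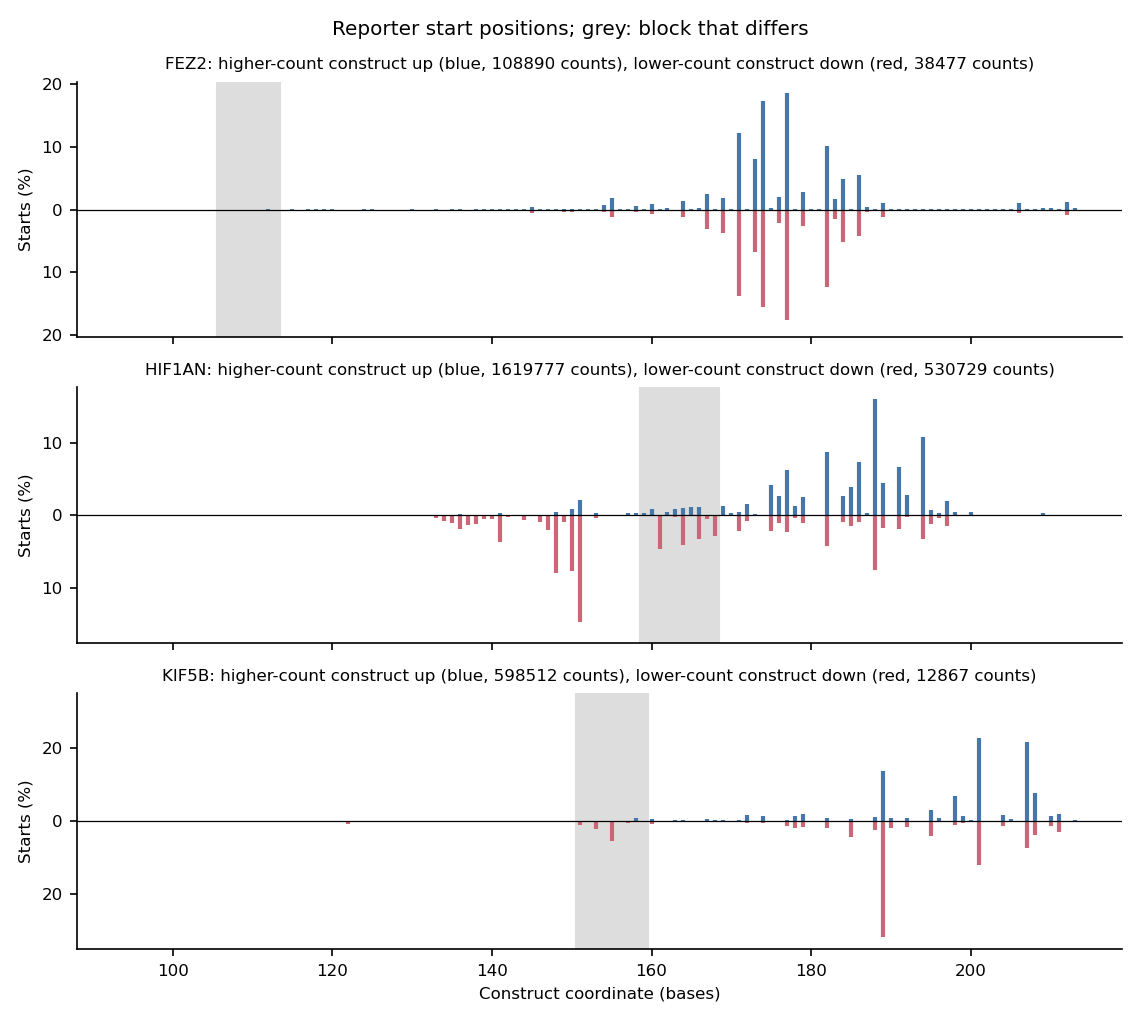
Share of reporter starts (%) by construct coordinate (bases) for the 3 pairs, the construct with more counts pointing up in blue and its altered partner down in red; grey marks the block that differs. Starts upstream of the block appear in the altered HIF1AN construct (48.01%), whereas the FEZ2 profiles nearly coincide.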

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

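All alternatives on retained bases, on the weighting of deletions and on left-out targets were chosen after seeing the data. The number of retained bases was the setting that ended the most calls. With at least 20, 4 targets had a lower main-start share in place of 7, and 3 had ends moved upstream in place of 8. Of the 4, C1orf63 (−0.346 points) and TMED9 (−0.544) were barely below 0, against −9.08 at RBM4 and −10.1 at NDUFV3. The median change was −1.09 points (p = 0.0879 in the exact test) and the mean shift 0.0370 bases; at single targets the shift turned to −1.85 bases at C1orf63, −0.184 at IRF1 and −4.76 at TMED9, and at LETMD1 it reached −5.66 (intervals below 0 at TMED9 and LETMD1), while it stayed upstream at EDEM2 (4.41), NDUFV3 (4.35) and RBM4 (1.79). In this setting the main start held over 5% of the expected ends in only 6 targets. With at least 12, the change shrank to −16.3 points at EDEM2, −11.4 at IRF1, −2.79 at LETMD1 and −0.295 at HSF1. It stayed near its main value at RBM4 (−12.3) and TMED9 (−19.97). In that setting the median change was −11.4 points and the mean shift 2.21 bases, both still past the threshold. Both results also kept their direction and side of the threshold in all 26 runs without 1 target (median change −15.6 to −14.1 points, mean shift 3.13 to 3.88 bases). They did so too with no filter on positions, with at least 30 ends per position, with deletions of at least 3 bases, as tallied, with deletions weighted equally, and in the 9 deepest targets. With deletions of at least 3 bases 9 targets had a lower main-start share, and with at least 30 ends per position 8. The shift at IRF1 fell from 7.73 to 4.09 bases with no filter on positions and to 3.42 with at least 12 retained bases, and its interval then spanned 0. As tallied, the mean shift was 7.77 bases and 11 targets had ends moved upstream, with LETMD1 at 5.43. The edited share of all ends moved from 62.2% to 58.2% with deletions of at least 3 bases and to 60.9% with deletions of at least 10 ends. Summed in 5-base windows, the share of reporter starts placed differently was 6.07% for FEZ2, 53.03% for HIF1AN and 38.8% for KIF5B. Within 50 bases of the main start it was 56.8% for HIF1AN. No paired analysis was possible because the deposited list does not separate the 2 libraries. For the same reason the planned runs with other size factors, DESeq2, no replicate block, each replicate left out or counts per library were not run. Depth limits IRF1, EDEM2, TXNRD2 and SOCS1, which have 31, 53, 35 and 4 unedited ends.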

Other observations

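Of the tests below, those of near starts by deletion length, of repeats with each allele counted once, of the LETMD1 start and of the AARATGGC element were chosen after related values had been seen. Abundant deletions tended to have the same bases at both ends. Among deletions of 3 to 40 bases over the most deleted base, the share of edited ends whose deletion had at least 2 repeated bases at its ends was a median of 70.2% over 12 targets. All placements of the same lengths over that base gave a median of 35.1%, with equivalent placements each counted, which raises this value. The mean excess was 26.3 percentage points (11 of 12 targets, exact sign-flip p = 0.000977), largest at TMED9 (44.1 points) and IRF1 (43.5 points). LETMD1 had −0.913 points, with an expected share of 93.1% when placements are weighted by the lengths of its edited ends. With each possible allele counted once, the expected median was 20.3% and the mean excess 38.5 points (12 of 12 targets, LETMD1 at 2.26). Counted in the same way but over distinct deletions in place of ends, the medians were 17.6% and 9.89% and the mean excess 9.12 points (12 of 12 targets, exact two-sided p = 0.000488). Repair through short repeats may favour these deletions; since each deletion is weighted by its RNA ends, a higher output of some alleles would add to the excess and stays open.

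The upstream movement of ends on edited alleles may be in part a loss of edited reads with a deletion close to their 5′ end, which stays open: the mean shift among ends with at least 20 retained bases was 0.0370 bases (p = 0.967, exact two-sided test over 13 targets), but it averages targets that went both ways and the main start was in view in only 6. A placement of ends too far upstream by the length of the deletion is argued against as the main cause over targets. Ends at exactly that distance exceeded the share given by other deletions by a mean of only 0.819 points (8 of 13 targets, exact sign-flip p = 0.0469). The excess ran from −0.486 points at TXNRD2 to 2.00 at EDEM2 and 4.07 at IRF1, so a part of the movement at single targets is not excluded. A loss set by distance and deletion length alone is also argued against, because for deletions of 3 to 9 bases and starts 12 to 15 bases upstream the ratio of near to far starts was 13.8 times larger at LETMD1 (1.89, 0.622 to 4.29) than at C1orf63 (0.137, 0.103 to 0.283). This was the later of 2 windows tried: in the earlier one (deletions of 1 or 2 bases, starts 14 to 16 bases upstream, 5 targets) all intervals overlapped, and over all 9 windows of length and distance 49 of 194 pairs of targets, in 8 windows, had intervals apart, with no correction for their number and some of them resting on few or no near ends. LETMD1 and C1orf63 lie on opposite strands, where the same counted distance can differ for deletions that can be moved. For deletions of 3 to 9 bases and starts 12 to 15 bases upstream, LETMD1 also lay apart from TMED9 (0.35, 0.25 to 0.52), on its own strand. A true effect of the deleted sequence on the nearest starts stays open, since nearness to the deletion and nearness of the start to the edited motif are the same in this design.

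The LETMD1 start 9 bases upstream of the main start has the same spacing as the length of its most frequent deletion. Of 14 other deletions with at least 20 ends, 0 had more ends at their own length than at 9 bases upstream, and 14 had fewer. This count alone decides little. On unedited RNA the place 9 bases upstream already held 2.95% of the ends, against 1.25% at 7 bases, the most used of the other places. Some of the 14 also rested on 1 to 3 ends against 0. The deletions with 471 ends (11 bases) and 1126 ends (1 base) put only 3.40% and 0.355% of them at their own length. These values argue against a start that moves with the deletion as the whole cause. The share of ends at this start was 34.9% with 9-base deletions and 20.0% with all others, but it varied within both. It was 46.4% and 28.8% with the 9-base deletions that begin at 51048333 and 51048338. It was 52.9% with an 11-base deletion that begins at 51048329 and 5.95% with the most frequent 1-base deletion. Where it was 46.4% and 52.9%, the main start held 1.06% and 2.12% of the ends. On these alleles only 6 and 2 bases separate the main start from the deletion, and starts that close are almost never seen. These shares, which enter the 34.9% and 20.0%, therefore do not separate greater use from missing main-start ends. With 11 and 14 retained bases, the main start held 30.6% (deletion at 51048338) and 60.6% (1-base deletion). Loss of reads near the deletion would not raise the nearer start more than the farther one. Ends 9 bases upstream, which lie closer to the deletion, gained 6.27-fold (2.48 to 10.8) relative to ends 20 bases upstream. These places were the largest matched gain and the largest matched loss outside the main start, so a ratio above 1 was likely from the choice. The unedited ratio rests on 26 and 49 ends. The interval does not cover this choice, and such a loss is not excluded. Greater use of this start on some edited alleles may be real, as a hypothesis found and tested on the same ends.

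The sequence AARATGGC, which resembles the binding site of YY1, lies near the deletions of C19orf43, ECI1, HSF1, LETMD1 and TMED9, by a search of the reference sequence. If its loss lowered main-start use, deletions that touch it should do so more than deletions that spare it. Only 3 targets had 100 ends of each kind, and the main start was lower with deletions that touch the element in 1 of them, ECI1 (0.807 of the matched unedited share against 0.902, with overlapping intervals of the differences). At TMED9 the values were 0.720 and 0.633, also with overlapping intervals. At C19orf43 they were 1.47 and 1.15, which decides nothing. Its element, at 12734653 to 12734660, covers the downstream start at 12734660 and lies close to the larger one at 12734663. Deletions that touch the element therefore also reach or approach these starts. An effect of the element stays open.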
